A study of Mus musculus with 24 samples.

How the data were processed

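RNA from the mammary glands of female mice was hybridised to Illumina bead arrays, 1 array per sample. The 24 samples come from 2 genotypes, wild type (WT) and homozygous for a LacZ allele of Snai2 (null), and from 4 cell populations of each genotype: luminal, basal and stromal cells separated by CD49f and Epcam at the cell surface, and unsorted cells. Each of the 8 groups has 3 arrays, numbered as the labels number them. Groups were taken from the labels alone, and every signal column matched 1 sample by its name. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Slides are not named in the sources used here and could not be used as a block.

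The deposited values are probe intensity on a linear scale for 25697 probes per array, not normalized and without background subtraction, per the file headers and the range of the values. A detection p-value per probe and array was deposited beside each intensity, per the file headers. These p-values are multiples of 1 over 798, as a rank against 798 negative control probes would give. A second deposited table holds linear intensities of the same arrays. They had a Spearman correlation of 1 with the first table on each array checked, and differed from a quantile normalization of it by at most 0.0124 on the log2 scale, with array medians from 111.79 to 112.03. That table was therefore read as quantile-normalized intensities, uncentred, and was used only as an alternative. The scanner software, its version and the steps before export are not given in the sources used here, and labels give only the RNA kit and the biotin label.

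Background was estimated from the detection p-values and removed with the normexp model, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. A probe was kept when its detection p was below 0.05 on at least 3 of the 24 arrays, which left 17878 probes. Symbols in the array file were brought up to date through a RefSeq gene table (assembly GRCm38.p6), used only for names and the order of neighbouring genes, so no coordinates are given. Of the probes, 20733 carried a current symbol, 3872 were updated through a synonym that belongs to 1 gene, 1092 matched none and kept the name in the file, and 32 had a symbol turned into a date or number. The 24 passing probes among these 32 were left out as unnamed. Each gene was represented by its passing probe with the highest mean over the 24 arrays, which gave 12552 genes, 3526 of them with more than 1 passing probe.

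A linear model with 1 mean per group was fitted to all 24 arrays with lmFit, so that all groups share an estimate of the spread, and tested with eBayes of limma. The comparisons were null against WT in each of the 4 populations, the 3 pairs of sorted WT populations, and the difference between the null effects in basal and luminal cells. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p below 0.05. All tests are two-sided. Log2 changes are given with the standard error (SE) of the fit, and levels as mean log2 intensity with the SD over 3 arrays. The number of arrays limits the precision: the median SE of a log2 change was 0.301, and 3 arrays against 3 make only 10 splits of the samples. Where a probe was not detected on any array of the dimmer group, the change is given as at least N-fold, the brighter group's mean against the higher, per array, of the dim probe's own value and the lowest signal among detected probes.

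Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, and again with a correlation estimated from the data (statmod 1.5.0), adjusted over the 28 lists within each comparison. The lists are basal keratin, adhesion and transcription factor genes, contractile genes, luminal keratin, tight junction and transcription factor genes, luminal progenitor genes, hormone-sensing luminal genes, milk genes, epithelial junction and splicing genes known as targets of the Snail family, epithelial-mesenchymal transition genes, and fibroblast, pericyte, endothelial, macrophage, lymphocyte, adipocyte, red cell, skeletal muscle and Schwann cell genes. The others are cell cycle, interferon response, immediate early and heat shock, Wnt pathway, Notch pathway, squamous, p53 response, TGF-beta response, cholesterol synthesis, oxidative phosphorylation and cytosolic ribosomal protein genes. The luminal keratin list and the Snail-target list each have 8 members that another list also holds, and the endothelial, macrophage and Schwann cell lists have 0. For each list the count of genes past the threshold is given over all genes tested and adjusted over the list alone.

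Groups, comparisons, tests, gene lists, alternative settings and the rule for the genes named were fixed before the data were examined. That rule takes, among genes past the threshold with a gene name that is no clone or predicted name and detected on all 3 arrays of the higher group, the 10 with the largest rise and the 10 with the largest fall in each null comparison, and 6 and 6 in the others. It adds up to 4 members per list with the smallest adjusted p, the 5 genes with the smallest p where fewer than 5 passed, genes that passed in the same direction in 3 or more null comparisons, and up to 3 members of a list that did not pass. Genes of the sort are named only as a check of the gates. Some genes that the rule takes are not reported here.

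Whether WT luminal and WT basal profiles shift in null basal cells was measured without reusing arrays. Genes at least 4-fold apart between the luminal and basal arrays of 1 WT replicate were taken, and their change was computed from the 3 null basal arrays against the other WT basal arrays, for each of the 3 replicates. These settings were no background correction, an offset of 50, median scaling, the second table, no filter, 2 stricter filters, every probe tested, only the arrays compared, a block for the replicate number, a random block for the sample code, an intensity trend with a robust prior, array weights, an adjusted p below 0.01, a minimum of 2-fold, signature limits of 2-fold and 8-fold, and leaving out each array. The block for the replicate number took that number across genotypes in the 4 null comparisons. For the pairs of WT populations and the difference it took the sample code, which is the number within a genotype. A block and separate fits for an unlabelled split of the arrays were chosen after seeing the data. The replicate numbers were checked as pairs through the correlation of the arrays' deviations from their group means. Between WT populations every pair of arrays with the same number correlated above 0.1, from 0.178 to 0.498 over the 6 pairs of populations. Paired WT samples would give this. The unlabelled split, which sets WT replicate 3 apart, would give part of it too. WT stromal replicate 2 was at 0.294 with WT unsorted replicate 1 and at 0.213 with replicate 2. Arrays with the same number did not all correlate above 0.1 between null populations, with a lowest value of -0.0865. Nor did they between genotypes, with a lowest value of -0.223.

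The fit was tested on simulated intensities for the 12552 genes before use. For null against WT basal cells, with 50 genes changed at each size, it recovered 26% of genes changed 2-fold, 56% at 3-fold, 58% at 4-fold and 64% at 8-fold, with median estimated folds of 1.84, 2.74, 3.42 and 6.48, and 9 of its 111 calls were unchanged genes. For null against WT luminal cells with nothing changed it called 0 genes. Regroupings of the real luminal, basal and stromal arrays across genotypes gave up to 26, 201 and 466 genes. The simulated counts of false calls therefore hold for the simulated intensities and do not give the rate of false calls on these arrays.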

Results

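Gene expression was measured in mammary gland cells of WT mice and of mice null for Snai2, the gene of Slug, a transcriptional repressor of the Snail family known to act on epithelial junction genes. Luminal, basal, stromal and unsorted cells of both genotypes were each measured on 3 arrays, 24 in all. Median raw intensity ranged from 93.6 to 143.71 per array, and from 12634 to 15825 of the 25697 probes were detected. Snai2, the deleted gene, had 0 probes under its symbol or a synonym, so its level was not analysed here and did not check the genotype labels. Of the surface markers of the sort, Epcam also had 0 probes. Itga6, which encodes CD49f, had a mean log2 intensity of 9.63 ± 0.15 in WT basal, 8.42 ± 0.67 in WT luminal and 5.60 ± 0.98 in WT stromal cells (SD, n = 3). In null cells its means were 9.76 ± 0.16, 8.85 ± 0.36 and 6.03 ± 0.19 in the same order.

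The leading principal components held 37.3% and 17.6% of the variance and separated luminal, basal and stromal arrays. The third, with 9.79%, separated arrays in a way that no label gives. On its positive side lay 11 arrays, replicates 1 and 2 of each WT population and replicate 1 of null luminal, basal and stromal cells, and the other 13 lay on its negative side. This unlabelled split crosses genotype and population in sorted cells, while all 3 null unsorted arrays lay on the negative side. The highest correlation between 2 arrays was 0.979, between null basal replicates 2 and 3, and no arrays were treated as duplicates.

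**Figure D1:**
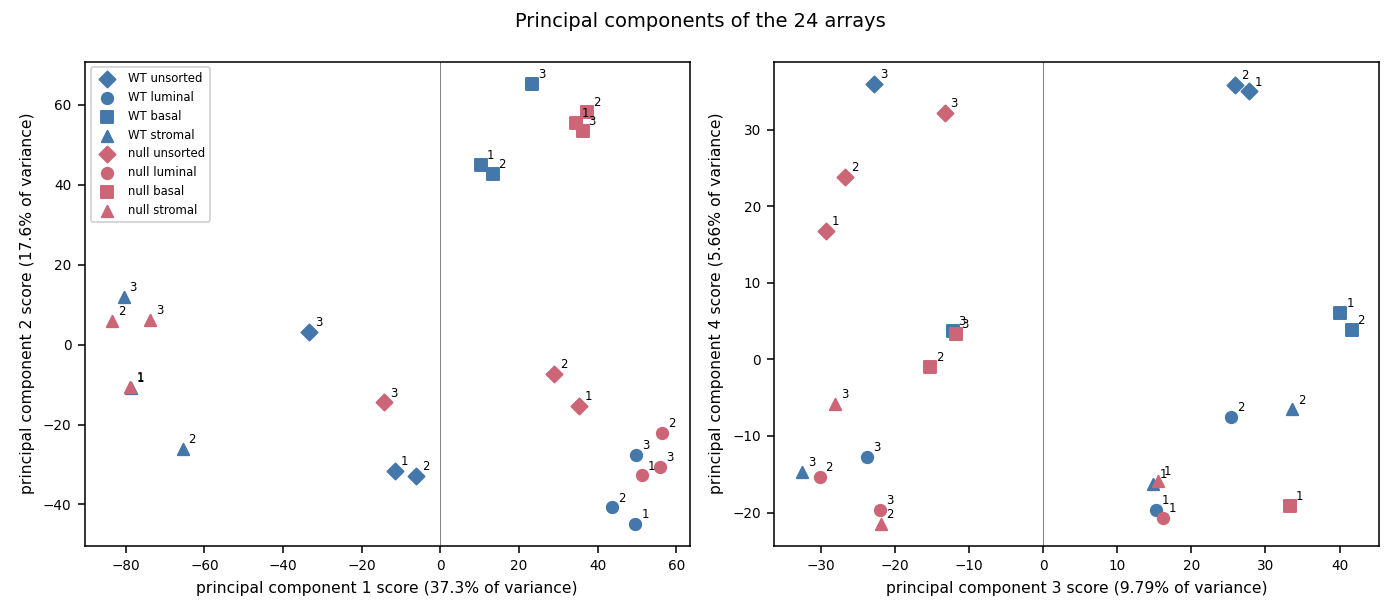
Scores of the 24 arrays on principal components 1 and 2 and on components 3 and 4, each point an array coloured by genotype and marked by population. Population separates on the first pair, while component 3 places replicates 1 and 2 of each WT population apart from replicate 3.

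The sorted WT populations were compared to describe the cells on which the null effect was measured. WT basal cells were higher than WT luminal cells for Reln, a secreted matrix protein (log2 change 4.01 ± 0.37, SE, adjusted p = 6.38e-07, n = 3 per group), Wnt10a, a Wnt ligand (3.67 ± 0.50), and Actg2, smooth muscle gamma actin (3.56 ± 0.33). The transcription factor gene Irx4 was not detected in WT luminal cells and was at least 7.17-fold higher in basal cells. Luminal cells were higher for Ido1, a tryptophan-degrading enzyme (basal over luminal -4.62 ± 0.61, adjusted p = 2.43e-05), the water channel gene Aqp5 (-4.00 ± 0.64) and the keratin gene Krt7 (-3.72 ± 0.39). Cited1 and Foxa1, regulators in hormone-responsive luminal cells, were not detected in basal cells and were at least 8.18-fold and 4.71-fold higher in luminal cells. Of 12552 genes, 1904 passed, 939 higher in basal and 965 higher in luminal cells. On the negative side of the unlabelled split 722 genes passed, from 1 array of each population, assumed to vary like the other groups.

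Of 20 basal keratin, adhesion and transcription factor genes, 18 were higher in WT basal than luminal cells (19 adjusted over the list alone), such as Lamb3, a laminin chain (2.68 ± 0.26), and Fst, which encodes the activin inhibitor follistatin (3.56 ± 0.36). So were 12 of 18 contractile genes (12 adjusted over the list alone), 9 of 20 Wnt pathway genes (11 adjusted over the list alone) and 10 of 20 TGF-beta response genes (11 adjusted over the list alone). Of 20 luminal keratin genes, 14 were lower in basal cells (16 adjusted over the list alone), as were 13 of 16 hormone-sensing genes (14) and 6 of 14 luminal progenitor genes (6). Also lower were 6 of 14 milk genes (6) and 13 of 25 Snail-target genes (16). Examples were Krt19 (-3.07 ± 0.29), the oestrogen receptor gene Esr1 (-2.09 ± 0.25), Aldh1a3, a retinaldehyde dehydrogenase (-3.24 ± 0.30), and the casein gene Csn3 (-3.10 ± 0.56). Of these 9 list shifts, that of the TGF-beta response genes was lost with an estimated correlation (camera adjusted p = 2.32e-06, adjusted p = 0.0723 with an estimated correlation). Epithelial-mesenchymal transition genes (5 of 23 higher, 1 lower, including Vim at 1.75 ± 0.39) and fibroblast genes (5 of 24 higher, 1 lower) shifted upward in basal cells, and oxidative phosphorylation genes downward, with 32 of 34 changes negative. Their adjusted p were 0.00141, 0.0034 and 0.00459, and adjusted p = 0.278, 0.591 and 0.346 with an estimated correlation. Markers of nerve-associated Schwann cells were also higher in WT basal than luminal cells for 3 of 8 genes, among them Cdh19 (1.86 ± 0.32), with an adjusted p = 0.0622 for the list.

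WT stromal cells were higher than WT basal cells for matrix and protease genes such as Htra3, a serine protease (basal over stromal -5.45 ± 0.50, adjusted p = 2.13e-07), Loxl1, a collagen crosslinking enzyme (-5.29 ± 0.43), and Lum, a matrix proteoglycan (-4.44 ± 0.44). Basal cells were higher for the keratin genes Krt5 (5.59 ± 0.37, adjusted p = 3.42e-09), Krt17 (5.12 ± 0.39) and Krt15 (at least 27.9-fold). In all, 1069 genes were higher in basal and 1209 in stromal cells. Between WT luminal and stromal cells 1552 genes were higher in luminal and 1531 in stromal cells. Ido1 (4.25 ± 0.61, adjusted p = 2.48e-05) and Prom2, a membrane protein of the prominin family (3.83 ± 0.84), were on the luminal side and Lox, a collagen crosslinking enzyme (-4.70 ± 0.40), and Mfap5, a microfibril protein (-4.69 ± 0.55), on the stromal side. On the negative side of the unlabelled split, again with 1 array of each population, 1253 and 1783 genes passed in these 2 comparisons, and with only the arrays compared 1338 passed in the first. Median scaling gave 755 higher and 1116 lower genes for basal over stromal cells, and 1060 higher and 1492 lower genes for luminal over stromal cells.

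All 24 fibroblast genes were lower in WT luminal than stromal cells and 23 of 24 lower in basal than stromal cells (24 and 23 adjusted over the list alone), and so were 17 and 11 of 23 epithelial-mesenchymal transition genes (18 and 13). Twist1, a transcription factor of mesenchymal cells, was not detected in WT basal cells and was at least 6.13-fold higher in stromal cells. All 20 luminal keratin genes and 22 of 25 Snail-target genes were higher in luminal than stromal cells (20 and 22 adjusted over the list alone), among them Krt18 (2.54 ± 0.25) and the tight junction gene Marveld3 (3.26 ± 0.33). Against stromal cells, basal cells were higher for 17 of 20 basal keratin genes, 11 of 18 contractile genes and 9 of 20 Wnt pathway genes (17, 12 and 9 adjusted over the list alone), and lower for 1, 3 and 1. These 9 list shifts held with an estimated correlation. A further 9 lists for basal and 10 for luminal over stromal cells shifted with the preset correlation alone, with adjusted p between 0.063 and 0.45 with an estimated correlation. Among them were pericyte genes such as Pdgfrb (at least 3.57-fold lower in basal cells), and skeletal muscle genes such as Myl1 (at least 5.59-fold lower in basal cells). Others were interferon response genes (7 of 20 lower in basal and 8 lower in luminal cells) and oxidative phosphorylation genes (4 of 34 higher in basal and 13 in luminal cells).

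Slug is known as a factor of basal mammary cells, and of the sorted populations basal cells had the most genes that differed between genotypes. In null basal cells 3 of 25 Snail-target junction genes were higher, and 2 of 8 Schwann cell, 1 of 21 endothelial and 3 of 16 adipocyte genes lower, than in WT basal cells. With an estimated correlation the Schwann cell list held, while the Snail-target, endothelial and adipocyte lists had adjusted p = 0.101, 0.14 and 0.139 with an estimated correlation. The highest rise was that of Bex4, a small brain-expressed X-linked protein, which had a mean log2 intensity of 9.00 ± 0.27 in null cells (SD, n = 3) and was not detected on any WT basal array. It rose by 4.63 ± 0.29 on the log2 scale (SE, at least 17-fold, adjusted p = 7.45e-09). Its relative Bex1 rose by 3.90 ± 0.37, a value that is uncertain because genes of this family are similar in sequence. Pkp2, a desmosomal plaque protein (3.20 ± 0.28, adjusted p = 1.6e-06), Cldn7, a tight junction claudin (2.89 ± 0.30, adjusted p = 9.05e-06), and Lcp1, an actin-bundling protein of blood cells (2.81 ± 0.28, at least 5.72-fold), rose too. Other rises were those of the nuclear pore gene Nup210 (3.16 ± 0.50), the keratin gene Krt73 (3.05 ± 0.48), the cytokine subunit gene Il23a (2.50 ± 0.31) and Ppp1r9a, an actin-binding protein of neurons (at least 4.13-fold). Falls were seen for Aoc3, a vascular amine oxidase (-3.12 ± 0.50), Cygb, a globin of fibroblasts and pericytes (-2.88 ± 0.40), and Lpl, a lipase of fat and muscle (-2.78 ± 0.48). Nrp1, a semaphorin and VEGF co-receptor (-2.52 ± 0.41), fell too.

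In this comparison 105 of 12552 genes passed, 56 higher and 49 lower in null basal cells, and 100 of them differed at least 2-fold. With only the 6 basal arrays in the fit 22 passed, within the negative side of the unlabelled split, which holds 1 WT basal array, 21, and with median scaling 61, 28 of them higher and 33 lower. Array weights raised the count to 770, 383 of them higher and 387 lower. Leaving out 1 array gave 53 without WT basal replicate 1, 59 without WT basal replicate 2, 201 without WT basal replicate 3, 44 without null basal replicate 2, and between 70 and 79 without the other null basal arrays. Of the 30 named genes past the threshold, 12 passed in each alternative that tested them on the arrays of both sides, among them Bex4, Bex1, Pkp2, Cldn7, Lcp1, Nup210, Il23a, Ppp1r9a, Aoc3, Cygb and Cdh19.

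**Figure D2:**
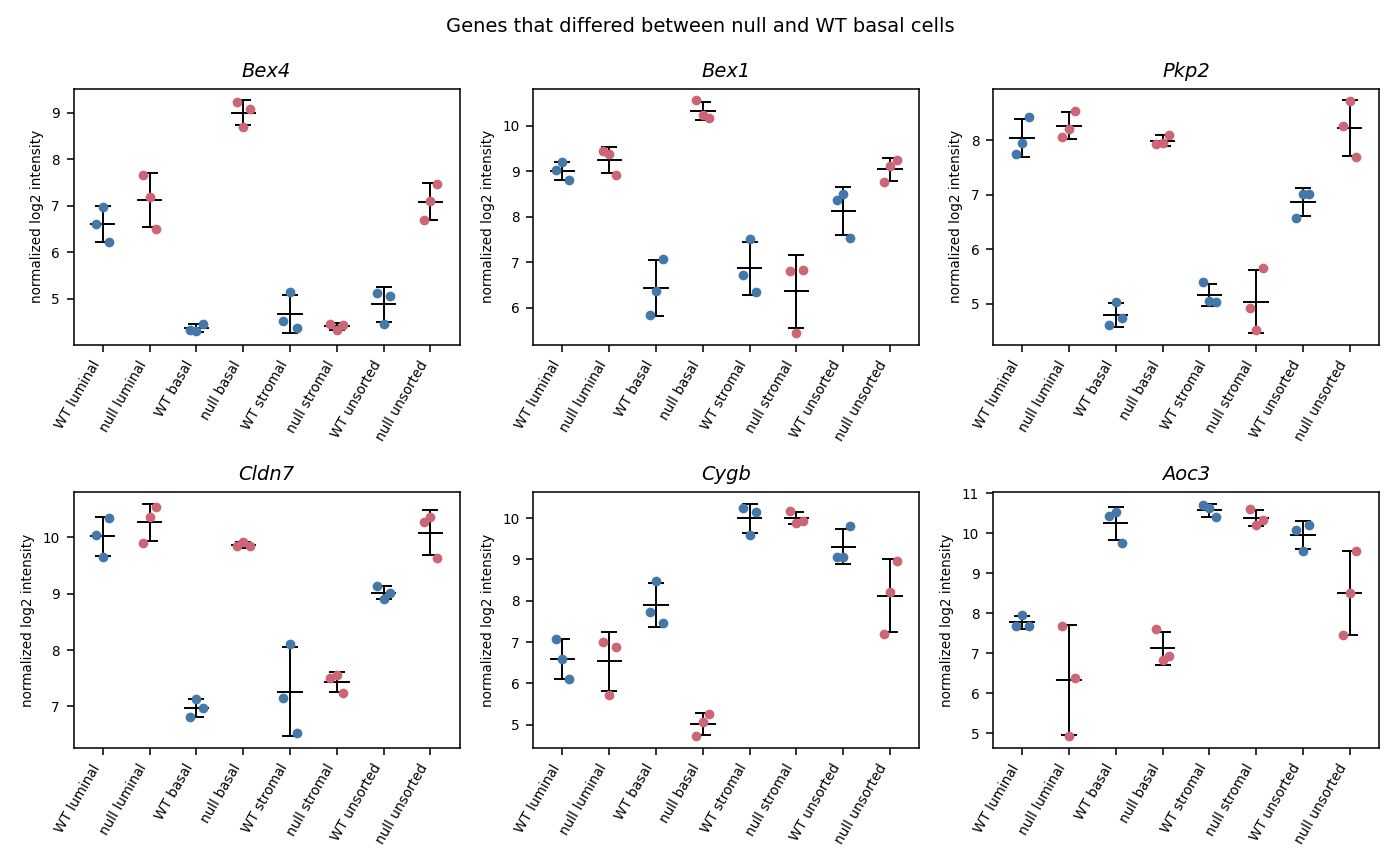
Log2 intensity of Bex4, Bex1, Pkp2, Cldn7, Cygb and Aoc3 in each of the 8 groups, with a point per array, a line at the mean of 3 arrays and bars of 1 SD, WT in blue and null in red. Bex4 lies at 9.00 ± 0.27 in null basal and at 4.37 ± 0.08 in WT basal cells, and Cygb and Aoc3 fall from WT to null in basal cells.

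Of 25 measured junction and splicing genes known as Snail-family targets, 3 rose in null basal cells and 0 fell (10 rose adjusted over the list alone): Cldn7, the tight junction gene Ocln (2.30 ± 0.43, at least 3.82-fold) and Marveld3 (1.52 ± 0.33). Changes of 23 of the 25 were positive, with Cldn4 at 2.00 (adjusted p = 0.0992) and Cldn3 at 1.80 (adjusted p = 0.122). The list shifted upward (camera adjusted p = 1.07e-11), but not with an estimated correlation between genes (adjusted p = 0.101 with an estimated correlation). Of 20 luminal keratin, tight junction and transcription factor genes, 2 rose, Cldn7 and the protease inhibitor gene Spint1 (1.36 ± 0.32), 6 adjusted over the list alone, while Krt8 was at 0.29 and Gata3 at -0.65 and neither passed. That shift had an adjusted p = 7.18e-06, and adjusted p = 0.239 with an estimated correlation. Mvd, an enzyme of the mevalonate pathway, was the 1 of 17 cholesterol synthesis genes that passed (at least 2-fold higher, 1 adjusted over the list alone). Positive changes were found for 15 of the 17 (adjusted p = 1.21e-06, adjusted p = 0.14 with an estimated correlation). Dsc3, a desmosomal cadherin (1.84 ± 0.41), was the 1 of 17 squamous genes that passed (2 adjusted over the list alone), with an adjusted p = 0.00134 for the list and adjusted p = 0.16 with an estimated correlation.

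The lists of endothelial, Schwann cell, adipocyte and fibroblast genes shifted downward in null basal cells with the preset correlation, and that of the Schwann cell genes also with an estimated one. All 21 endothelial genes had negative changes with a median of -1.43, and Flt1, a VEGF receptor, passed (at least 2.26-fold lower, 12 genes adjusted over the list alone, camera adjusted p = 1.5e-14, adjusted p = 0.14 with an estimated correlation). The mean endothelial score was 0.91, 0.28 and -0.94 in WT basal replicates 1, 2 and 3 and -1.34, -1.07 and -0.99 in null basal cells, so that WT replicate 3, on the negative side of the unlabelled split, lay near the null arrays. Among 8 Schwann cell genes 2 fell, including Cdh19 (at least 2.62-fold lower), and adjusted over the list alone 3 fell and 1 rose, with Mbp at 1.36 (adjusted p = 0.285). This list shifted downward also with an estimated correlation (adjusted p = 0.000596 and adjusted p = 0.0364 with an estimated correlation), and its scores of 0.31, 0.40 and 0.41 in WT basal cells lay above all 3 null values, -0.45, -0.22 and -0.23. Of 16 adipocyte genes 3 fell (6 adjusted over the list alone, adjusted p = 4.53e-06, adjusted p = 0.139 with an estimated correlation), Lpl, the fatty acid carrier Cd36 (-1.80 ± 0.39) and the hormone gene Lep (at least 1.89-fold). Of 24 fibroblast genes Col6a1 (-2.27 ± 0.53) and Col6a2 (-1.83 ± 0.40) fell (5 adjusted over the list alone, adjusted p = 1.07e-11, adjusted p = 0.173 with an estimated correlation). Fibroblast scores were -0.69, -0.59 and -0.97 in WT and -1.92, -1.46 and -1.46 in null basal cells.

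Lists without a gene past the threshold over all genes also shifted in null basal cells with the preset correlation. Immediate early and heat shock genes were lower for 18 of 22 (4 adjusted over the list alone, adjusted p = 0.000209, adjusted p = 0.173 with an estimated correlation). Epithelial-mesenchymal transition genes were lower for 18 of 23 (3 adjusted over the list alone, adjusted p = 0.00194, adjusted p = 0.287 with an estimated correlation). Positive changes were found in 16 of 21 cell cycle genes and 30 of 34 oxidative phosphorylation genes (0 adjusted over the list alone in both), with adjusted p = 0.0013 and 0.000897, and adjusted p = 0.287 and 0.267 with an estimated correlation. The cell cycle shift was lost without null basal replicate 3 (adjusted p = 0.149) and the oxidative phosphorylation shift without WT basal replicate 2 (adjusted p = 0.0661). The other 16 lists did not pass in null basal cells: adjusted p was 0.146 for basal keratin genes, 0.0802 for contractile genes, 0.144 for macrophage genes, 0.146 for pericyte genes, 0.468 for luminal progenitor genes and 0.63 for hormone-sensing genes. It was 0.209 for milk genes and for interferon response genes, 0.304 for lymphocyte genes, 0.216 for red cell genes, and 0.994 for skeletal muscle genes. For pathway lists it was 0.815 for Wnt pathway genes, 0.169 for Notch pathway genes, 0.772 for p53 response genes, 0.814 for TGF-beta response genes and 0.146 for ribosomal protein genes. Notch pathway and p53 response genes passed in 0 of the 8 comparisons.

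**Figure D3:**
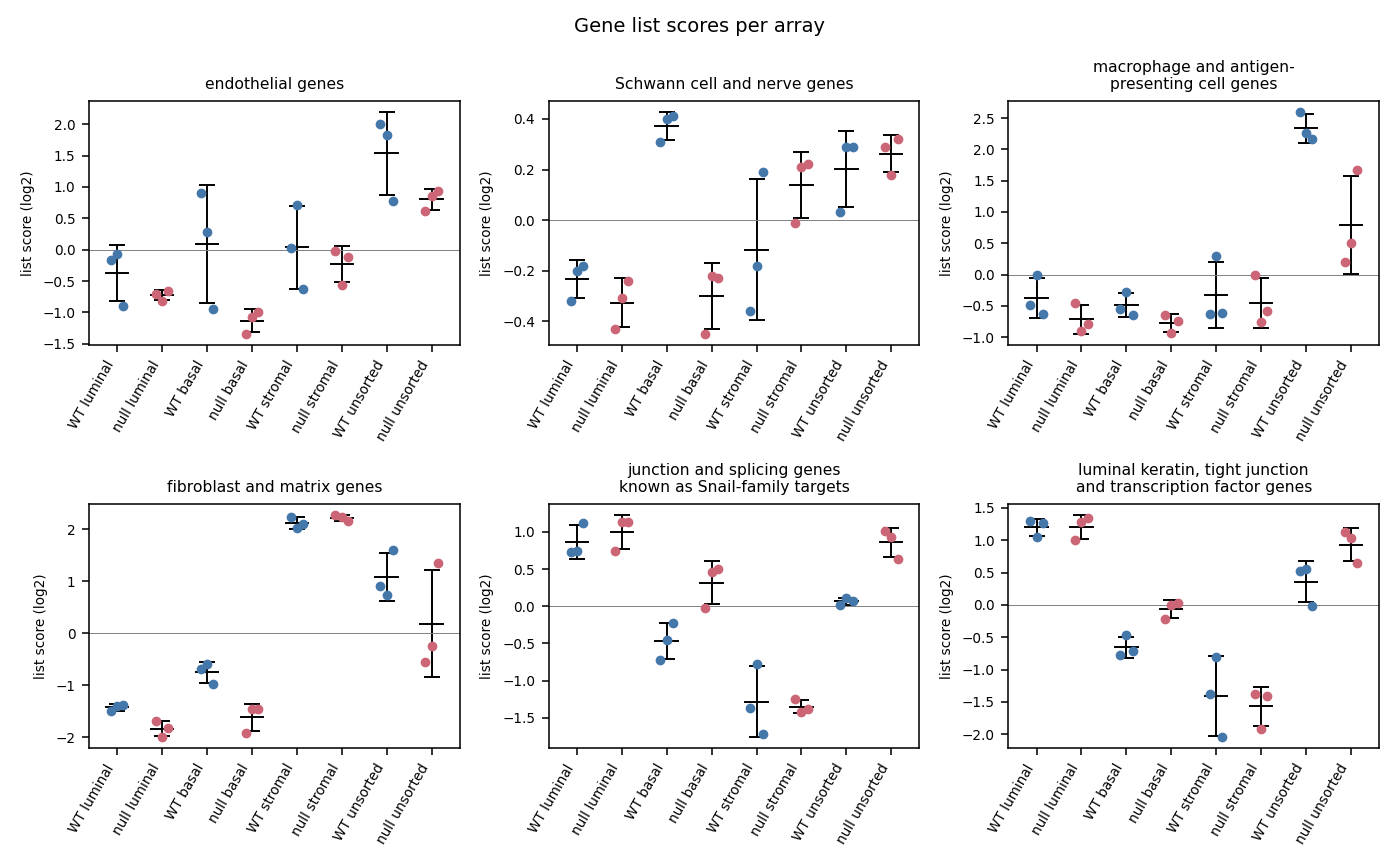
Mean score of 6 gene lists (endothelial, Schwann cell, macrophage, fibroblast, Snail-target junction and luminal keratin genes) in each group, in log2 units relative to each gene's mean over the 24 arrays, with a point per array, a line at the mean and bars of 1 SD (n = 3), WT in blue and null in red. Endothelial scores of WT basal cells spread from 0.91 to -0.94, and macrophage scores of unsorted cells lie at 2.60, 2.26 and 2.16 in WT and at 0.20, 0.50 and 1.67 in null cells.

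Whether null basal cells lie nearer to the WT luminal profile was measured with genes at least 4-fold apart between WT luminal and WT basal cells, with no array used in both steps. Luminal-high genes had median log2 changes of 0.18, 0.28 and 0.03 in null basal cells for the 3 WT replicates that set the genes, a median of 0.18. Basal-high genes had medians of -0.20, -0.17 and -0.10, a median of -0.17. The 3 values are not replicates, since each uses the same 3 null basal arrays and each WT basal array is the reference in 2 of them. Without background correction the medians were 0.06 and -0.05, and the second deposited table gave 0.07 and -0.05. With 1 null basal array left out they ranged from 0.10 to 0.26 and from -0.28 to -0.09. No test was run on these medians.

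Null luminal cells differed from WT luminal cells at 1 gene, Upk2, a urothelial membrane protein, which fell by 1.30 ± 0.20 on the log2 scale (adjusted p = 0.0249, n = 3 per group). At an unadjusted p below 0.05, 433 genes were counted. The 4 genes next in order did not pass, among them Ctsa, a lysosomal protease (-1.35 ± 0.28), Ndufab1, a mitochondrial acyl carrier protein (-1.09 ± 0.21), and the kinase gene Pdk3 (1.07 ± 0.23). Their adjusted p lay between 0.213 and 0.279. Upk2 did not pass with median scaling (adjusted p = 0.239), with only the luminal arrays in the fit (0.998), or without WT luminal replicate 1 (0.138), 2 (0.0914) or 3 (0.127) or null luminal replicate 2 (0.0799). Among the lists, fibroblast genes were lower for 22 of 24 (median -0.40, camera adjusted p = 0.000242), macrophage genes lower for 16 of 18 (adjusted p = 0.0453) and cell cycle genes higher for 17 of 21 (adjusted p = 0.00985). Each had 0 genes past the threshold, also adjusted over the list alone, and adjusted p = 0.833 with an estimated correlation. The macrophage shift was lost without WT luminal replicate 2 (adjusted p = 0.364) or null luminal replicate 2 (0.215) or 3 (0.211), and the cell cycle shift without WT luminal replicate 2 (0.234) or null luminal replicate 2 (0.0699).

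The difference between the null effects in basal and luminal cells was tested in the same fit. It passed for 21 genes, 18 with a more positive effect in basal cells and 3 with a more negative one, while 542 genes were counted at an unadjusted p below 0.05. The effect in basal minus that in luminal cells was 4.11 ± 0.41 for Bex4 (adjusted p = 3.12e-05), 3.66 ± 0.53 for Bex1, 2.97 ± 0.39 for Pkp2, 2.67 ± 0.40 for Lcp1 and 2.64 ± 0.42 for Cldn7. The transcription factor gene Foxq1 (2.79 ± 0.55) and Mvd (1.43 ± 0.26) had higher, and Cygb (-2.83 ± 0.57) and Brinp3, a neuronal protein (-1.62 ± 0.31), lower effects in basal cells. With the sample code, the number within a genotype, as a block the calls of Foxq1 (adjusted p = 0.106), Cygb (0.0813) and Brinp3 (0.0531) ended. Bex4, Foxq1, Lcp1 and Mvd were detected on 0 of the 3 WT basal arrays and Brinp3 on 0 of the luminal arrays, so their differences are fitted against undetected levels and give no exact size or order. In luminal cells the null effect was 0.52 for Bex4, 0.23 for Pkp2 and 0.25 for Cldn7. With median scaling 5 genes passed, and with only the arrays compared 12. The sides of the unlabelled split taken apart gave 0 and 0, but each has 1 array in 1 genotype of both populations, assumed to vary like the other groups, so these counts say nothing on stability. Without each in turn of WT luminal replicates 1, 2 and 3, WT basal replicates 1 and 2 and null basal replicates 2 and 3, between 9 and 13 passed. Of the 10 genes that the rule for names takes, Bex4, Bex1 and Pkp2 passed in each alternative that used the arrays of both sides.

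Lists whose null effect differed between basal and luminal cells with the preset correlation alone were the Snail-target genes (20 of 25 positive, adjusted p = 5.51e-07, adjusted p = 0.264 with an estimated correlation) and luminal keratin genes (17 of 20, 0.000119 and 0.354 in the same order). Others were the cholesterol synthesis genes (15 of 17, 3.6e-05 and 0.325), oxidative phosphorylation genes (30 of 34, 0.000368 and 0.354) and squamous genes (13 of 17, 0.0319 and 0.354). Negative differences were found for endothelial genes (20 of 21, adjusted p = 9.18e-07, adjusted p = 0.354 with an estimated correlation), immediate early and heat shock genes (21 of 22, 2.48e-05 and 0.264) and adipocyte genes (12 of 16, 0.00154 and 0.354). The same holds for fibroblast genes (17 of 24, 0.00376 and 0.708) and Schwann cell genes (6 of 8, 0.00379 and 0.115). The fibroblast difference was lost without null basal replicate 1 (adjusted p = 0.103) and the adipocyte difference without WT basal replicate 1 (0.0571). The squamous difference was lost without each of 7 arrays in turn, up to adjusted p = 0.431 without WT luminal replicate 3.

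Null stromal cells differed from WT stromal cells at 3 genes. Bmp8a, a bone morphogenetic protein, rose (1.47 ± 0.22, adjusted p = 0.00648), and Kcnn1, a calcium-activated potassium channel (-2.10 ± 0.24, adjusted p = 0.000444), and Dhtkd1, a mitochondrial dehydrogenase subunit (-1.53 ± 0.21, adjusted p = 0.00395), fell. At an unadjusted p below 0.05, 558 genes were counted. Flt1 at -1.67 ± 0.31 (adjusted p = 0.0901) and the protease gene Mmp27 at -0.74 ± 0.14 (adjusted p = 0.0926) did not pass. With only the stromal arrays in the fit 0 genes passed, and without WT stromal replicate 1, 1 passed. Without that array Bmp8a (adjusted p = 0.0858) and Dhtkd1 (0.0553) did not pass, and without WT stromal replicate 2 Bmp8a did not (0.0671). Without WT stromal replicate 3 the count was 6, and without null stromal replicates 1, 2 and 3 it was 5, 7 and 8.

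Lymphocyte genes (13 of 16 positive, 1 adjusted over the list alone, adjusted p = 0.0148) and skeletal muscle genes (11 of 14 positive, 0 adjusted over the list alone, adjusted p = 0.0148) shifted upward in null stromal cells, both with adjusted p = 0.93 with an estimated correlation. So did ribosomal protein genes (22 of 27 positive, 0 adjusted over the list alone, adjusted p = 0.00769, adjusted p = 0.93 with an estimated correlation). The skeletal muscle score was 1.60, 1.29 and -0.26 in WT and 2.43, 0.64 and 0.98 in null stromal cells. The direction of that list turned without WT stromal replicate 3 (adjusted p = 0.826) or null stromal replicate 1 (adjusted p = 0.984). The lymphocyte shift was lost without the same arrays (adjusted p = 0.114 and 0.643), and the ribosomal shift without WT stromal replicate 2 (0.63) or null stromal replicate 3 (0.078).

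In unsorted null cells the list of macrophage genes was lower than in unsorted WT cells, with 4 of 18 genes past the threshold, and 5 genes rose, 1 of them (Ovol1) from the lists. Falls were seen for Fcna, a ficolin of macrophages (-2.70 ± 0.31, adjusted p = 0.000367), F13a1, a coagulation factor subunit (-2.66 ± 0.42), and the chemokine gene Pf4 (-2.51 ± 0.51). The complement genes C1qc (-2.17 ± 0.27), C1qb (-2.09 ± 0.39) and C1qa (-2.08 ± 0.30) fell too. Bex4 (2.21 ± 0.29, adjusted p = 0.000532), Abcc8, a subunit of a potassium channel (1.63 ± 0.25), Ovol1, an epithelial transcription factor (2.11 ± 0.40), Pkp2 (1.36 ± 0.28, adjusted p = 0.0408) and Vmn1r65, a vomeronasal receptor gene (2.43 ± 0.51), were the 5 that rose. In all, 35 genes passed, 30 of them lower in null cells, and 1471 were counted at an unadjusted p below 0.05. With only the unsorted arrays in the fit 0 passed, with a filter on at least 12 arrays 2, and within the negative side of the unlabelled split, which holds 1 WT unsorted array, 0. With median scaling 17 passed, 5 of them higher and 12 lower. Array weights gave 394, 143 of them higher and 251 lower. Leaving out null unsorted replicate 3 gave 503 genes and WT unsorted replicate 3 gave 80, while without the other arrays between 15 and 19 passed. Of the 17 genes named for this comparison 7 passed with each array left out in turn.

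All 18 macrophage genes had negative changes in null unsorted cells, with a median of -1.34. List scores were 2.60, 2.26 and 2.16 in WT and 0.20, 0.50 and 1.67 in null unsorted replicates 1, 2 and 3. Null replicate 3 thus lay nearer to WT. The complement genes C1qa, C1qb and C1qc and the receptor gene Csf1r (-1.34 ± 0.22) passed, 15 adjusted over the list alone, and Mrc1, a mannose receptor, was at -2.69 (adjusted p = 0.0616). This list held with an estimated correlation (adjusted p = 5.28e-22, and adjusted p = 0.0418 with an estimated correlation). With the unlabelled split as a block as well it did not (camera adjusted p = 0.0696 with an estimated correlation). Other lists shifted with the preset correlation alone. Fibroblast genes had negative changes for 23 of 24 (0 past over all genes, 10 adjusted over the list alone, adjusted p = 6.41e-11, adjusted p = 0.227 with an estimated correlation). So had 21 of 23 epithelial-mesenchymal transition genes (3 adjusted over the list alone, 9.91e-07 and 0.169 in the same order) and 20 of 21 endothelial genes (Lyve1, a lymphatic receptor, at -2.04 ± 0.39, 1 adjusted over the list alone, 4.5e-06 and 0.305). Adipocyte (15 of 16), pericyte (9 of 10), red cell (4 of 5) and interferon response genes (14 of 20) had negative changes as well, with adjusted p = 0.000813, 0.00363, 0.00545 and 0.0344, and adjusted p = 0.227, 0.169, 0.227 and 0.305 with an estimated correlation. Changes were positive for 21 of 25 Snail-target genes (Ovol1 past, 11 adjusted over the list alone, adjusted p = 4.32e-10, adjusted p = 0.169 with an estimated correlation) and 17 of 20 luminal keratin genes (3 adjusted over the list alone, 1.5e-05 and 0.24). The same holds for 13 of 17 cholesterol synthesis genes (2 adjusted over the list alone, 0.00136 and 0.286) and 16 of 17 squamous genes (0 adjusted over the list alone, 0.00326 and 0.227). Without single arrays the pericyte, red cell and interferon shifts were lost, with adjusted p up to 0.0713 and 0.106 for the first 2 without null unsorted replicate 3 and WT unsorted replicate 2, and 0.146 for the third without WT unsorted replicate 2.

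**Figure D4:**
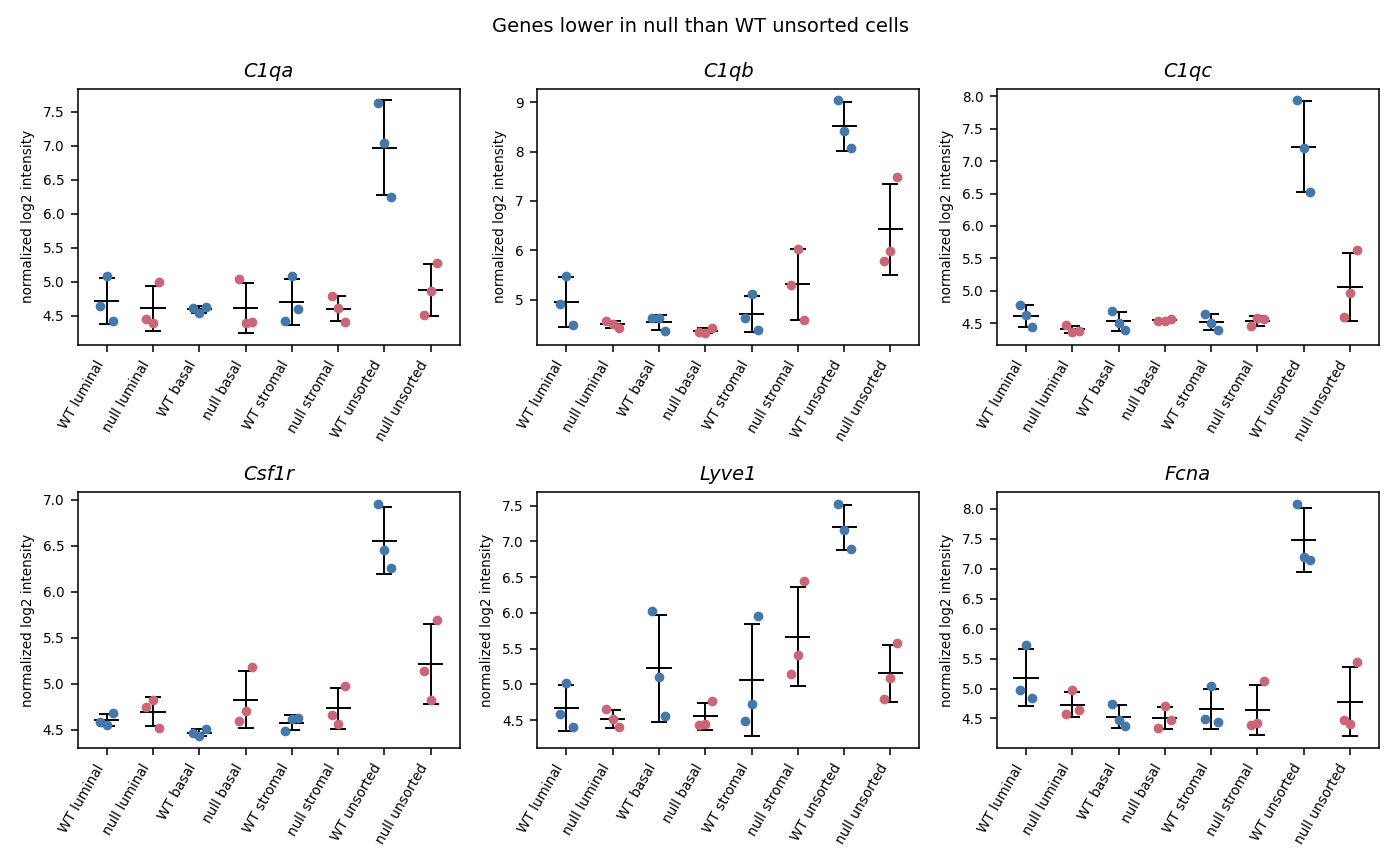
Log2 intensity of C1qa, C1qb, C1qc, Csf1r, Lyve1 and Fcna in each of the 8 groups, with a point per array, a line at the mean of 3 arrays and bars of 1 SD, WT in blue and null in red. In unsorted cells the null arrays lie below the WT arrays on average, by 2.08 on the log2 scale for C1qa and 2.70 for Fcna.

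Bex4 and Pkp2 were higher in null cells both in the basal and in the unsorted population, 2 shared genes where independent lists would share 0.0223. No gene fell in both, where 0.117 would be shared, and 0 genes passed in the same direction in 3 populations. The unsorted and basal comparisons share no arrays, but WT basal and WT unsorted samples with the same number correlate, from 0.219 to 0.453, so the comparisons are not independent. Unsorted samples also include basal cells, so a rise within basal cells can show in both. The value for independent lists is therefore no measure of recurrence in a separate population. Without null unsorted replicate 3, 38 genes were shared between at least 2 populations, and with array weights 73. Over all 224 pairs of a list and a comparison, 80 shifts passed with the preset correlation and 19 of them with an estimated correlation. These were 8 lists for WT basal over luminal, 5 for WT basal over stromal and 4 for WT luminal over stromal cells, Schwann cell genes in null basal cells and macrophage genes in null unsorted cells. A list's median, mean and test differed in sign in 27 of the 224 pairs, none of them past the threshold, as for hormone-sensing genes in null basal cells (median 0.04, mean -0.03).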

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

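The tests on the unlabelled split of the arrays, on fewer endothelial or Schwann cells and on raised genes within 2 standard errors of luminal cells were chosen only after the result was seen. The null effect differed between basal and luminal cells at 21 genes by a test of the difference itself, which is what singled these results out, and 20 of the 21, all but Upk2, also passed between genotypes in basal cells. The difference, basal minus luminal, was 4.11 for Bex4, 3.66 for Bex1, 2.97 for Pkp2, 2.79 for Foxq1, 2.67 for Lcp1, 2.64 for Cldn7 and 1.43 for Mvd. It was -2.83 for Cygb and -1.62 for Brinp3. Bex4, Foxq1, Lcp1 and Mvd were detected on 0 of the 3 WT basal arrays and Brinp3 on 0 of the luminal arrays, so their values are fitted against undetected levels and give no exact size or order. With the sample code, the number within a genotype, as a block the calls of Foxq1 (adjusted p = 0.106), Cygb (0.0813) and Brinp3 (0.0531) ended. Those of the other 6 did not. Of 100 splits of the 12 basal and luminal arrays, 8, the real one included, gave at least 21 genes and the highest other gave 116, so chance is not excluded for this count. This share is no value without an effect: 10 of the 100 keep the WT and null basal arrays apart, 6 of the 8 and the split with 116 among them, while of the 90 others 2 gave as many, up to 53. The splits also regroup basal and luminal arrays separately, although WT luminal and basal arrays with the same number correlate, from 0.192 to 0.416.

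The 56 genes raised in null basal cells were weighed against luminal cells in the null basal samples, cells that the sort on CD49f and Epcam would remove. Luminal cells of the average profile cannot raise a gene above its mean level in luminal cells. By over 2 standard errors, 30 of the 56 lay higher in null basal than in null luminal cells. The null basal arrays enter both values of this comparison. The luminal level is a mean over all cells of the gate, so a luminal subset with a higher level is not excluded. The 7 that lay lower would need a median luminal share of 43.1%. Random sets of the 252 luminal-high genes showed from -1.63% to 16.4% (5th and 95th percentile of 10000 sets). The median over these 252 genes was 4.67%. Krt8, abundant in luminal cells, was at 10.36 ± 0.26 in WT and 10.65 ± 0.60 in null basal cells. Scores of the whole luminal keratin list, however, were -0.77, -0.47 and -0.72 in WT and -0.22, 0 and 0.03 in null basal cells. A small share of luminal cells would give such a rise too. The 19 within 2 standard errors, which lie at the luminal level by choice, need a share of at least 53%. Random sets of 19 luminal-high genes showed a share of up to 10% (95th percentile). The 7 and the 19 were chosen for their rise, so a need above that of random sets is no evidence by itself. That choice does not fix the low share that luminal-high genes showed. It argues against average luminal cells at a share as large as the 19 need. A smaller share or a luminal subset stays open for these parts. With the unlabelled split as a block 55 of the 56 passed, which argues against that split as the whole cause. Loss of Slug, which the design names, stays open as a hypothesis and was not tested here, and Snai2 had 0 probes.

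The lists of endothelial and Schwann cell genes, 21 and 8 measured and 0 of them held by another list, shifted downward in null basal cells, with 1 and 2 genes past the threshold, and the endothelial shift did not hold with an estimated correlation (adjusted p = 0.14). With the unlabelled split as a block they had adjusted p = 2.46e-12 and 0.000149 (adjusted p = 0.152 and 0.0213 with an estimated correlation), which argues against a shift of 1 size between the sides as the whole cause. Over genes detected on every WT basal array, however, the endothelial medians were -2.49 on the positive side, which holds 1 null basal array, and -0.15 on the negative side (Schwann cell genes -1.91 and -1.84). Fewer endothelial cells cannot be told apart from a change within cells, because 100% of the 11 genes detected on every WT basal array were lower but all 21 changes of the list were negative to begin with, with Cldn5 at 8.52 ± 1.31 in WT and 6.57 ± 0.64 in null and Esam at 8.25 ± 1.25 and 6.39 ± 1.06. Fewer Schwann cells stay open as well because 75% of only 4 genes were lower, while Mbp was at 6.43 ± 0.98 and 7.79 ± 0.54, and a gate on Epcam would remove cells of either type that lack it.

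The 18 macrophage genes, 0 of them held by another list, were lower in null unsorted cells, and a candidate explanation is another mix of cells in samples that no sort had narrowed. Across 12552 genes, which are not independent replicates, the unsorted null effect had a Spearman rho of 0.341 with the WT luminal over stromal difference. It was 0.307 with the basal over stromal difference, as more epithelial and fewer stromal cells would give. An exchange of sorted stromal for sorted epithelial cells alone would not lower macrophage genes, however. Their list scores were -0.63, 0.29 and -0.62 in WT stromal, -0.48, -0.01 and -0.63 in WT luminal and 2.60, 2.26 and 2.16 in WT unsorted cells. A larger epithelial share could still lower them by leaving a smaller share to macrophages. Null unsorted replicates 1, 2 and 3 had macrophage scores of 0.20, 0.50 and 1.67 and fibroblast scores of -0.55, -0.24 and 1.36. Fibroblast scores in WT unsorted cells were 0.92, 0.73 and 1.60. The correlation therefore does not decide whether fewer macrophages were present. The most abundant macrophage genes, which did not pass over all genes, had means of 10.48 ± 0.07 in WT and 9.08 ± 0.91 in null cells for Laptm5, 10.42 ± 0.12 and 9.29 ± 0.91 for H2-Ab1, and 10.07 ± 0.28 and 8.73 ± 0.57 for Cd74. With the unlabelled split as a block the list had a camera adjusted p = 4.06e-19. The median change went from -1.34 to -1.23 and 3 of the 4 genes past the threshold passed. With an estimated correlation the adjusted p went from 0.0418 to 0.0696 with the block. All null unsorted arrays, but only replicate 3 of WT unsorted cells, lay on the negative side. The block's shift per gene thus came largely from sorted cells, where macrophage scores were low. The block therefore cannot decide whether the split lowered macrophage genes in unsorted cells. A genotype effect on macrophages stays open and was not tested apart from the mix of cells.

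Splits of the 6 arrays number 10 in each comparison of 2 groups, the real one included, too few for a share under 0.05. Null against WT gave 1 gene in luminal, 105 in basal, 3 in stromal and 35 in unsorted cells, and the highest other split gave 26, 201, 466 and 118. The first 3 of these highest splits, WT replicates 1 and 2 with null replicate 1, follow the unlabelled split, and with that split as a block the real counts were 1, 142 and 3. In unsorted cells the highest split set WT replicates 1 and 3 and null replicate 3 apart from the others. Splits that call several times the real count point to a structure of the samples. Between WT populations the counts were 1904 for basal and luminal, 2278 for basal and stromal and 3083 for luminal and stromal cells, and the highest other split gave 2 in each.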

How the results depend on the processing

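The block for the unlabelled split of the arrays and the fits within its sides were tests chosen only after the result was seen, that is after seeing the data. Counts below are of genes past the threshold in null against WT cells of a population, in a pair of WT populations, or in the difference of the null effects between basal and luminal cells. Values of a list are the comparisons, of 8, in which it shifted. The stricter threshold lowers a count by its construction, and for all other settings the cause was not tested. Within a side, null sorted groups on the positive side and all WT groups on the negative side are 1 array each, assumed to vary like the groups with more, so a count there says nothing on the stability of a result. With an adjusted p below 0.01 the counts were 0 in luminal, 49 in basal, 16 in unsorted cells, 1118 for basal over luminal, 1425 for basal over stromal, 2023 for luminal over stromal and 9 for the difference. With only the arrays compared they were 0 in luminal, 22 in basal, 0 in stromal, 0 in unsorted, 1338 for basal over stromal and 12 for the difference, with 0 genes shared between populations. On the positive side of the split they were 0 in luminal, 1 in stromal and 0 for the difference, and unsorted cells gave no value because no null array lies there. On the negative side they were 21 in basal, 0 in unsorted, 722, 1253 and 1783 for the pairs of WT populations in the order above and 0 for the difference, with 0 shared. Detection on at least 12 arrays gave 0 in luminal, 0 in stromal and 2 in unsorted cells, 0 for lymphocyte, red cell and skeletal muscle genes, 4 for Schwann cell genes and 1 shared gene.

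Median scaling gave 0 in luminal, 61 in basal (28 higher, 33 lower), 17 in unsorted (5 higher, 12 lower) and 5 for the difference (5 higher, 0 lower). It gave 690 lower and 758 higher genes for basal over luminal cells, 0 higher and 2 lower in stromal cells, 2 for luminal progenitor, 5 for endothelial, 2 for lymphocyte and 5 for ribosomal protein genes, 1 shared gene and a basal-high median of -0.289 in place of -0.167. It moved the median of all genes in unsorted cells by 0.156 on the log2 scale, from 0.0104 to 0.166, and by less than 0.1 elsewhere. Array weights gave 770 in basal, 394 in unsorted and 52 for the difference, 5 for endothelial, 0 for lymphocyte, 2 for red cell and 5 for immediate early genes and 73 shared genes. The trend with a robust prior gave 7 in stromal cells and 1 shared gene. No filter gave 9 in stromal cells, 4 for contractile, 2 for progenitor, 1 for macrophage, 2 for lymphocyte and 4 for immediate early genes and 1 shared gene. Every probe tested gave 4 for contractile, 2 for progenitor, 2 for lymphocyte and 2 for red cell genes and 4 shared genes. The block for the unlabelled split gave 23 in unsorted cells, 2 for progenitor, 1 for macrophage and 1 for Notch genes and 1 shared gene. No background correction gave 1 for macrophage and 2 for lymphocyte genes and a basal-high median of -0.0511 (48 higher and 29 lower genes in basal cells), and the second deposited table gave 1, 2 and -0.0529. In these 2 settings the luminal-high median was 0.0576 and 0.0677 in place of 0.178. An offset of 50 gave 1 for macrophage genes and -0.113, and a detection p below 0.01 gave 1 for macrophage and 0 for red cell genes.

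With an estimated correlation between genes, luminal keratin genes went from 6 to 2 comparisons, hormone-sensing 2 to 1, milk 2 to 1, Snail-target 6 to 2, epithelial-mesenchymal transition 5 to 2, fibroblast 7 to 2, macrophage 2 to 1 and Schwann cell genes 2 to 1. Pericyte, endothelial, lymphocyte, adipocyte, red cell, skeletal muscle, cell cycle, interferon, immediate early, squamous, TGF-beta, cholesterol, oxidative phosphorylation and ribosomal protein genes went to 0. The skeletal muscle shift in null stromal cells reversed with array weights (adjusted p = 0.96), without WT stromal replicate 3 (0.826) and without null stromal replicate 1 (0.984), while without the other stromal arrays its adjusted p was as low as 1.85e-05.

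The replicate block was the replicate number, which does not pair the genotypes, for null against WT cells. For the other comparisons it was the sample code. It gave counts of 1, 133, 3 and 33 in luminal, basal, stromal and unsorted cells. Counts were 2402, 2726 and 3610 for the pairs of WT populations and 14 for the difference. Under this block progenitor genes passed in 2, endothelial genes in 5 and macrophage genes in 1 comparison, and the WT luminal over stromal shift of basal keratin genes (adjusted p = 0.0565) and the null luminal macrophage shift (0.0626) were lost. It ended no other list call and moved no count by over 1.5 times. Calls of 6 named genes ended, Cabyr and Pf4 in unsorted cells, Mcm6 for basal over stromal cells and Brinp3, Cygb and Foxq1 for the difference. A random block for the sample code, with a consensus correlation of 0.152, gave 1, 100, 4, 34, 2323, 2692, 3581 and 24 in that order and has no list values. The slide as a block was not run because slides are not named.

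With each array left out in turn, where a group of 2 shares the spread of all groups, counts ranged from 0 to 2 in luminal, 44 to 201 in basal, 1 to 8 in stromal, 15 to 503 in unsorted cells and 9 to 20 for the difference. Ranges for the pairs of WT populations were 1308 to 1669, 1809 to 2272 and 2419 to 2916. Lists ranged from 1 to 2 comparisons for progenitor, 3 to 6 for endothelial, 1 to 2 for macrophage, 0 to 2 for lymphocyte, 0 to 2 for red cell, 2 to 4 for immediate early, 0 to 1 for Notch, 3 to 5 for squamous, 3 to 5 for oxidative phosphorylation and 1 to 3 for ribosomal protein genes. Luminal-high medians ranged from 0.102 to 0.258, basal-high medians from -0.285 to -0.0919 and shared genes from 1 to 38, the highest without null unsorted replicate 3.

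No gene named past the threshold changed direction in any setting run. Of the 105 genes past the threshold in basal cells, 59 were among the 61 with median scaling, 21 among the 22 with only the basal arrays, 14 among the 21 on the negative side, 41 among the 95 on the positive side, 103 among the 142 with the split as a block and 105 among the 770 with array weights. For the pairs of WT populations 69 of 83, 68 of 93 and 80 of 98 named genes passed in each setting that used the arrays of both sides, as did 12 of 30 in basal, 0 of 17 in unsorted, 0 of 3 in stromal and 0 of 1 in luminal cells and 3 of 10 for the difference. Signal over background limits dim genes: a gene detected in 1 group alone has only a bound on its fold.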

Other observations

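The test on neighbours of the deleted gene was chosen only after the result was seen. Among 16 Notch pathway genes the ligand genes Dll1, Jag1 and Jag2 and Lfng, a glycosyltransferase that modifies Notch receptors, were higher in WT basal than luminal cells, and the receptor gene Notch3 was higher in luminal cells. These genes were chosen after their values were seen. Dll1 and Jag2 were not detected on any WT luminal array and were at least 4.31-fold and 2.15-fold higher in basal cells, Jag1 was at 1.23 ± 0.29 (limma adjusted p = 0.00555) and Notch3 at -2.06 ± 0.41 (adjusted p = 0.0012). As a whole the list had a camera adjusted p = 0.115, and 0 of its genes passed between genotypes in the 4 populations.

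The casein gene Csn2 varied widely among arrays of a group. Its mean log2 intensity was 9.60 ± 1.44 in null and 5.73 ± 1.43 in WT luminal cells, and 7.95 ± 2.18 and 4.49 ± 0.11 in basal cells (SD, n = 3). Csn2 was detected on 0 of the 3 WT basal arrays, so its null basal mean was at least 8.19-fold higher (adjusted p = 0.25). The log2 changes were 3.87 in luminal (adjusted p = 0.757, detected on 2 of 3 WT arrays), 2.37 in unsorted (adjusted p = 0.425) and 1.44 in stromal cells, and none passed. In luminal cells Csn1s2a, not detected in WT, was at least 6.03-fold higher and Glycam1, detected on 1 of 3 WT arrays, was at 2.16, and neither passed over all genes, while 2 milk genes passed in luminal cells adjusted over the list alone. Other milk genes had negative changes in luminal cells, among them Csn1s2b (-0.82), Lalba (-0.53), Csn3 (-0.26) and Btn1a1 (-0.20), none of which passed. For milk genes as a list the camera adjusted p was 0.329 in luminal and 0.209 in basal cells.

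Pkp2, raised in null basal cells, lies near Snai2, 23 genes away in the order of the RefSeq table, so deletion of Snai2 or the strain of its flanks might change neighbouring genes. Of the 20 nearest measured genes, 10 on each side, 1 passed in null basal cells, namely Pkp2, whose rise was known beforehand. Of the closest, Abcc1 was at 0.09 (adjusted p = 1) and Efcab1 at 0.98 ± 0.31 (adjusted p = 0.238). The counts in luminal, stromal and unsorted cells were 0, 0 and 1. These counts argue only against large changes of many neighbours. The fit recovered 26% of genes changed 2-fold in simulated basal cells, so smaller effects could be missed. They stay open, as does an effect on Pkp2 alone.

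Null unsorted replicate 1 had a correlation of 0.946 with WT luminal replicate 3, above those with null unsorted replicates 2 (0.942) and 3 (0.934). On the first principal component null unsorted replicates 1 and 2 lay at 35.23 and 29.03, and replicate 3 at -14.23.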
